A study of Homo sapiens with 4 samples.

How the data were processed

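Bru-seq measures nascent RNA: cells take up bromouridine, a uridine analogue, and an antibody against it pulls down the RNA made while it was present. Per the labels' protocols, U2OS cells, a human osteosarcoma line, that stably overexpressed the decapping cofactor DCP1a fused to GFP were labelled with 2 mM bromouridine for 30 min, and RNA was taken with no chase. Hypertonic medium held 300 mM sodium and was made by adding concentrated phosphate-buffered saline, and isotonic medium held 150 mM sodium and received a matching volume of ordinary saline. The labels put 2 libraries in each group. They give neither the length of the exposure nor whether the replicates came from separate cultures. P-values of single genes therefore measure the spread between these libraries, which may be technical. The library protocol mentions actinomycin D for strand-specific reads in certain samples, without saying which.

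The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.3.3, STAR 2.5.3a and bedtools 2.16.2, and the builds hg38 and GRCh38, with no role for each tool. The annotation release is not given in the sources used here. Each deposited table had 105538 entries, 1 per gene and strand, for 57733 genes on 24 chromosomes, with 0 mitochondrial entries. The authors deposited an estimated count of reads per entry and an RPKM value; the tables have no header, and both meanings were read from the values. The deposited expected counts were not all whole: 73.9 to 79.6% of values above 0 and under 50 lay within 0.01 of a whole number. The deposited RPKM values were the count divided by gene length and by 1 constant per library. What that constant counts is not stated, and it exceeded the sum of the deposited counts in every library. Bases shared by genes that overlap on the same strand were excluded from the genes and pooled in 48 shared-region entries, which held 3.11 to 3.48% of counts and were left out. Counts of genes treated in this way rest on part of their length. Yet 401 sense-intronic and 168 snoRNA genes, types that lie mostly inside same-strand genes, had enough counts to be tested. How shared bases were assigned at such nested genes was not settled here.

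Of the genes used, 57428 had an entry for their own strand (sense) and 47490 an entry for the opposite strand (antisense). Strand and gene type were taken from GENCODE release 29 by unversioned Ensembl identifier, which matched 57429 genes, 77.9% of them with identical start and end; 45 copies on the Y pseudoautosomal regions and 259 genes without a match were left out (0.165 to 0.209% of counts). Coordinates are those of the deposited tables on GRCh38, counted from 1. Total counts were 28367788 and 23048409 in hypertonic replicates 1 and 2 and 44888307 and 23410787 in isotonic replicates 1 and 2. The sense strand of the genes used held 25068625, 20870648, 41932649 and 21865138 of them. The labels name no molecular identifiers, so counts are of reads, not of independent molecules, and values are given with the spread between libraries.

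Expected counts were rounded to whole numbers and sense counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors of 0.947, 1.22, 0.974 and 0.887, the default expression filter, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change (hypertonic over isotonic) is its size divided by the square root of F. CPM values use the effective library sizes. Gene lists were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the 24 lists with at least 5 tested members. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it. With the preset correlation camera compares genes with genes and takes them as nearly independent. Its small p-values for lists and classes therefore do not measure agreement between replicate libraries. Genes downstream of an active neighbour (the read-in class) started within 10 kb after the end of a same-strand gene whose isotonic level was at least 4 times their own; the convergent class ended within 5 kb of the end of an opposite-strand gene of that kind. Both classes were drawn from the 15372 tested genes with no same-strand overlap and compared with the rest of these by camera. Values per library were compared by exact two-sided permutation tests, for which 2 against 2 libraries cannot give a p below 0.333. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 under Python 3.11.15.

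The groups, tests, gene lists, classes and most alternatives were fixed before the data were examined. The genes named in the text followed a rule of the same date: up to 20 genes past the threshold over all genes (0 were), the 3 members of each list with the smallest p, and 12 set genes (DCP1A, CPSF6, NUDT21, NFAT5, AKR1B1, SLC5A3, SLC6A6, SGK1, FOS, EGR1, HSPA1A and MYC), which gave 81 entries. Neighbour pairs, genes named for their antisense counts and SLC38A2 were chosen after their values were seen. The antisense comparison was added after the data were examined. It used the antisense counts with the library sizes and TMM factors of the sense counts. Genes with a mean isotonic RPKM of at least 0.5 counted as active there.

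On counts simulated from these libraries with their own spread (20570 genes), the edgeR test called 0% of 45 genes changed 2-fold, 20.8% of 48 changed 4-fold, 58% of 50 changed 8-fold and 76% of 50 changed 16-fold, with 3 false calls. With a biological coefficient of variation of 0.1 (20842 genes) the shares were 82%, 98%, 100% and 100%, with 6 false calls. The list test found 19 of 20 simulated lists of 30 genes shifted by -0.6 and 0 of 20 unshifted lists at the libraries' own spread (20502 genes). With the smaller spread it found 20 of 20 and 1 of 20 (20784 genes). In all these simulations genes varied independently, so the list counts do not cover lists whose members vary together. The neighbour search was checked against a plain search for 300 genes of each kind and gave equal answers for all 300.

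Alternatives were other normalizations (RLE, total count, upper quartile), DESeq2 1.42.0, limma-voom, limma on log2(RPKM + 0.1, 0.5 or 1), no filter or stricter filters, overlapping genes left out, other distances, ratios and comparison sets for the classes, the replicate number as a block, and each library left out in turn. Where a library is left out, the lone library of its group is assumed to vary like the other group. Chosen after seeing the data were the removal of each library's trend on gene length, the upper-quartile scaling and the comparison with expressed protein-coding genes for the lists (with an estimated correlation and with each library left out), the choice of neighbours on other libraries, RLE and total-count scaling and protein-coding genes alone for the downstream class, the estimated correlation and read-in genes left out for convergent genes, and all antisense alternatives. Results for some single genes are not reported here.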

Results

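The series asked how nascent transcription differs between U2OS osteosarcoma cells in hypertonic and isotonic medium. Bromouridine-labelled RNA was sequenced from 2 libraries at 300 mM sodium and 2 at 150 mM, all from cells stably overexpressing GFP-DCP1a, a cofactor of mRNA decapping found in P-bodies. Hypertonic replicates 1 and 2 held 28367788 and 23048409 counts, and isotonic replicates 1 and 2 held 44888307 and 23410787. The 10 genes with the most counts took 2.17 to 2.75% of the sense counts of a library. Across 21238 tested genes, log2 CPM correlated at 0.972 between the isotonic libraries, at 0.891 between the hypertonic libraries, and at 0.887 to 0.947 between libraries of different groups. Genes are not independent replicates, so these correlations describe the libraries only.

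DCP1A (ENSG00000272886, chromosome 3, 53283428 to 53347610, minus strand), the gene the cells overexpress, measured 314 and 199 CPM in the hypertonic and 283 and 630 CPM in the isotonic libraries, a log2 fold change of -0.83 ± 0.50 (SE, n = 2 per group). Its entry overlaps another gene, and counts of the transgene and of the chromosomal gene were not told apart here. With TMM scaling, expressed protein-coding genes stood lower as a class in both hypertonic libraries. The 4828 with a mean RPKM of at least 1 had a median log2 fold change of -0.33, and 77.2% of them lay below 0. Their medians were -0.53 in hypertonic replicate 1 and -0.33 in replicate 2, relative to the isotonic mean. The 9695 protein-coding genes under that level had a median of 0.12, and the 6715 genes of other types a median of 0.34. These 3 values had no test of their own and were computed with TMM scaling only. The median of all tested genes was 0.04 with TMM and 0.26 by total count, so these medians also depend on the scaling.

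No gene passed the threshold over all 21238 genes in edgeR, where the lowest adjusted p was 0.192. At an unadjusted p under 0.05 there were 2316 genes, 1889 higher and 427 lower in the hypertonic libraries. The other tools called 0 genes (limma-voom) and 731 genes (DESeq2, 706 higher and 25 lower). In edgeR, no filter beyond a total count of 1 gave 916 genes (869 higher), and the replicate number as a block gave 384 (380 higher). Without hypertonic replicate 2 edgeR called 4919 genes (2557 higher and 2362 lower), without isotonic replicate 1 it called 6, without isotonic replicate 2 it called 4, and without hypertonic replicate 1 it called 0. Of the 596 genes that DESeq2 called higher and that overlapped no other gene on their strand, 340 (57.0%) lay just downstream of a more active neighbour, the class described after the gene lists. That share was 65.2% of 336 genes with the replicate block, 46.1% of 765 without a filter and 34.8% of 2036 without hypertonic replicate 2. The median log2 fold change of all tested genes was 0.04 with TMM, 0.01 with RLE, 0.26 by total count and 0.23 by upper quartile. With total count the genes at an unadjusted p under 0.05 split into 2179 higher and 111 lower, and with upper quartile into 2323 and 200.

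Ribosomal protein genes were lower in the hypertonic libraries: of 83 tested, 68 had a negative and 15 a positive fitted fold change, with a median of -0.60 (camera, adjusted p = 2.81e-11; adjusted p = 0.416 with an estimated correlation). In 45 of them both hypertonic libraries lay below both isotonic ones and in 3 above, where chance gives 16.7% in each direction and expressed protein-coding genes showed 38.7% below and 5.32% above. RPL9 (ENSG00000163682, chromosome 4, 39454124 to 39458948) measured 30.4 ± 0.657 CPM (SD, n = 2) against 93.3 ± 6.03 CPM (SD, n = 2), a log2 fold change of -1.62 ± 0.41 (SE). RPL7 (ENSG00000147604, chromosome 8, 73290284 to 73295789) measured 15.0 ± 0.847 against 52.96 ± 2.14 CPM, a log2 fold change of -1.82 ± 0.46, and RPL21, which overlaps another gene, one of -2.08 ± 0.45. SR proteins and CLK kinases, which act in splicing, were also lower, with 18 of 21 members negative and a median of -0.61 (camera, adjusted p = 1.48e-05; adjusted p = 0.416 with an estimated correlation). TRA2B (ENSG00000136527, chromosome 3, 185915906 to 185938136) measured 292 ± 52.8 against 906 ± 241 CPM (SD, n = 2 each), a log2 fold change of -1.63 ± 0.44. SRSF10 (ENSG00000188529, chromosome 1, 23964804 to 23980356) measured 76.4 ± 7.10 against 206 ± 21.3 CPM, a log2 fold change of -1.43 ± 0.38, while SRSF1 was at -0.79 ± 0.39. Over all genes 0 members of either list passed the edgeR test, while DESeq2 called 4 ribosomal genes lower, RPL21, RPL9 and RPL7 among them, and 0 SR members. Adjusted over the list alone, 2 SR members did (TRA2B and SRSF10, adjusted p = 0.0487) and 0 ribosomal ones. Without hypertonic replicate 2 the SR median was -0.97. Under total-count scaling the ribosomal and SR medians were -0.35 and -0.34.

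Genes that host snoRNAs in their introns were lower, with 21 of 29 members negative and a median of -0.65 (camera, adjusted p = 0.000303; adjusted p = 0.416 with an estimated correlation). TAF1D stood at -1.22 ± 0.38 (84.7 ± 14.9 against 198 ± 8.89 CPM, SD, n = 2 each), SNHG15 at -1.53 ± 0.50 and SNHG28, which overlaps another gene, at 2.11 ± 0.69. The median was -1.17 without hypertonic replicate 1 and -0.44 without hypertonic replicate 2, where the call was lost. Translation factors and aminoacyl-tRNA synthetases had 16 of 21 members negative and a median of -0.27 (camera, adjusted p = 0.00704; adjusted p = 0.429 with an estimated correlation). EIF5A stood at -0.99 ± 0.62, EEF1A1 at -0.84 ± 0.48 and EIF2S2 at -0.75 ± 0.45. The median was -0.05 under total-count and -0.08 under upper-quartile scaling, and the call was lost without isotonic replicate 2 (adjusted p = 0.0623). Ribosome biogenesis and RNA polymerase I genes had 23 of 30 members negative and a median of -0.20, but 0.07 under total-count and -0.03 under upper-quartile scaling (camera, adjusted p = 0.0041; adjusted p = 0.585 with an estimated correlation). In that list UTP15 was at -1.34 ± 0.58, UTP4 at -0.89 ± 0.41 and NOP2, an rRNA methyltransferase, at 1.13 ± 0.47. Its medians were -1.06 in hypertonic replicate 1 and 0.29 in hypertonic replicate 2. The median was 0.25 without hypertonic replicate 1, -1.08 without hypertonic replicate 2 and -0.47 without isotonic replicate 1. The call was lost without hypertonic replicate 1 and without isotonic replicate 2 (-0.09). In these 3 lists edgeR called 0 members over all genes and 0 adjusted over the list alone. DESeq2 called SNHG28 (adjusted p = 0.0476).

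Factors of mRNA cleavage and polyadenylation were lower, with 19 of 27 members negative and a median of -0.42 (camera, adjusted p = 0.0012; adjusted p = 0.416 with an estimated correlation). CPSF6 (ENSG00000111605, chromosome 12, 69239537 to 69274358), a subunit of cleavage factor I, measured 63.8 ± 23.4 against 147 ± 13.6 CPM (SD, n = 2 each), a log2 fold change of -1.20 ± 0.42. Its partner NUDT21 stood at -0.83 ± 0.51, CPSF7 at -1.06 ± 0.38 and WDR82 at -1.04 ± 0.43. The last 2 overlap other genes. P-body and mRNA decay components had 31 of 35 members negative and a median of -0.31 (camera, adjusted p = 0.000303; adjusted p = 0.416 with an estimated correlation). LSM3 stood at -1.21 ± 0.48, PNRC2 at -1.17 ± 0.47 and CNOT7 at -1.03 ± 0.43. Integrator and Mediator subunits had 25 of 32 members negative and a median of -0.25 (camera, adjusted p = 0.00206; adjusted p = 0.416 with an estimated correlation). MED6 measured 40.0 ± 8.78 against 103 ± 0.789 CPM (-1.36 ± 0.41), with MED10 at -1.96 ± 0.60 and MED31 at -1.70 ± 0.63. In these 3 lists edgeR called 0 members over all genes and 0 adjusted over the list alone. DESeq2 called MED10 (adjusted p = 0.0272). Both hypertonic libraries lay below both isotonic ones for 13 of 27, 13 of 35 and 10 of 32 members, respectively, next to 38.7% of expressed protein-coding genes. Of expressed protein-coding genes 77.2% had a negative fold change. Against these alone, a comparison chosen after seeing the data, the 3 lists did not pass (camera, adjusted p = 0.514, 0.514 and 0.931). Under total-count scaling the 3 medians were -0.23, -0.12 and -0.008, and under upper-quartile scaling -0.22, -0.10 and -0.06. Without hypertonic replicate 2 the medians were -0.74, -0.57 and -0.43.

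Genes of DNA replication were lower, with 24 of 28 members negative and a median of -0.34 (camera, adjusted p = 0.000303; adjusted p = 0.539 with an estimated correlation). Under total-count and upper-quartile scaling this median was -0.11 and -0.17. TYMS, which makes thymidylate, stood at -1.13 ± 0.52, RFC4 at -1.12 ± 0.52 and PCNA, which overlaps another gene, at -0.81 ± 0.44. Genes of mitosis had 19 of 27 members negative and a median of -0.19, but 0.04 under total-count and -0.01 under upper-quartile scaling, with the call lost both times (camera, adjusted p = 0.0255; adjusted p = 0.585 with an estimated correlation). CDK1, the mitotic kinase, measured 121 ± 24.4 against 278 ± 43.3 CPM (SD, n = 2 each), a log2 fold change of -1.20 ± 0.40, with CCNB1 and KIF23 at -0.86 each. In both lists 0 members passed over all genes, in edgeR or DESeq2, and 0 adjusted over the list alone in edgeR. The replication median was -0.20 without hypertonic replicate 1, -0.75 without hypertonic replicate 2 and -0.53 without isotonic replicate 2. The mitosis call was lost without hypertonic replicate 1 (-0.13) and without isotonic replicate 1, where the median was 0.06, and the median was -0.39 without hypertonic replicate 2 and -0.45 without isotonic replicate 2.

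Immediate early genes, NF-kB targets and YAP and SRF targets were lower on average but differed widely between libraries of 1 group. Immediate early genes had 31 of 42 members negative and a median of -1.20 (camera, adjusted p = 0.00305; adjusted p = 0.585 with an estimated correlation), while the median difference of isotonic replicate 2 from replicate 1 was 2.31. FOS measured 148 and 9.90 CPM in the hypertonic and 16.8 and 324 CPM in the isotonic libraries, EGR1 was at -1.86 ± 0.97, MYC at -1.29 ± 0.69, NR4A3 at -4.64 ± 1.62 and SIK1 at -2.59 ± 0.99. KLF6 measured 20.3 ± 6.25 against 75.1 ± 42.7 CPM (SD, n = 2 each), a log2 fold change of -1.89 ± 0.54. The list's median was 0.71 without isotonic replicate 2 and -0.56 without hypertonic replicate 2, with the call lost both times, and -2.12 and -1.93 without hypertonic and isotonic replicate 1. Without isotonic replicate 2, the log2 fold change of FOS was 2.19, the log2 fold change of EGR1 was 0.91 and the log2 fold change of NR4A3 was 1.27. NF-kB targets had 15 of 20 members negative and a median of -0.73 (camera, adjusted p = 0.00704; adjusted p = 0.585 with an estimated correlation). The cytokine genes CXCL8 and CCL20 stood at -4.54 ± 1.21 and -4.05 ± 1.17, and TNFAIP3 at -1.51 ± 0.58. CXCL8 measured 1.27 and 0.314 CPM in the hypertonic and 2.99 and 33.9 CPM in the isotonic libraries, and CCL20 0.845 and 0.511 against 1.52 and 21.1 CPM. Without isotonic replicate 2 the log2 fold changes of CXCL8, CCL20 and TNFAIP3 were -1.96, -1.20 and -0.69, those of KLF6 and MYC -1.18 and -0.18. The call was lost without hypertonic replicate 2 (-0.97) and without isotonic replicate 2 (-0.39), and the median was -0.48 without hypertonic replicate 1. YAP and SRF targets had 22 of 29 members negative and a median of -0.73 (camera, adjusted p = 0.000303; adjusted p = 0.585 with an estimated correlation). FHL2 stood at -1.63 ± 0.50, ANKRD1 at -1.54 ± 0.64 and TUFT1 at -1.07 ± 0.49. Its median was -1.11 without isotonic replicate 1 and 0.00 without isotonic replicate 2, where the call was lost. In these 3 lists edgeR called 0 members over all genes and 0 adjusted over the list alone. DESeq2 called KLF6 (adjusted p = 0.0499), CXCL8 (adjusted p = 0.000217) and CCL20 (adjusted p = 0.00146).

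Targets of ATF4 in the integrated stress response had 17 of 27 members negative and a median of -0.20, but -0.07 under total-count and 0.03 under upper-quartile scaling (camera, adjusted p = 0.0145; adjusted p = 0.416 with an estimated correlation). MTHFD2, an enzyme of mitochondrial folate metabolism, measured 73.1 ± 8.27 against 180 ± 25.4 CPM (SD, n = 2 each), a log2 fold change of -1.30 ± 0.39. GARS stood at -1.07 ± 0.44 and CEBPG at -1.51 ± 0.63. Targets of p53 had 18 of 26 members negative and a median of -0.22, but 0.04 under total-count and -0.05 under upper-quartile scaling, with the call lost both times (camera, adjusted p = 0.0454; adjusted p = 0.416 with an estimated correlation). AEN stood at -1.37 ± 0.56, CCNG1 at -1.19 ± 0.54 and MDM2 at -0.79 ± 0.41. Of expressed protein-coding genes 77.2% were negative. Against these alone, a comparison chosen after seeing the data, neither list passed (camera, adjusted p = 0.732 for ATF4 and 0.797 for p53 targets). In both lists 0 members passed over all genes, in edgeR or DESeq2, and 0 adjusted over the list alone in edgeR. The ATF4 call was lost without hypertonic replicate 2 (-0.58), and its median was -0.40 without hypertonic replicate 1, -0.05 without isotonic replicate 1 and -0.13 without isotonic replicate 2. The p53 call was lost without hypertonic replicate 2 (-0.58) and isotonic replicate 2 (-0.30), and its median was -0.40 without hypertonic replicate 1 and -0.08 without isotonic replicate 1.

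Osmoadaptive genes did not pass the test as a list: 18 of 24 members were positive, with a median of 0.29 (camera, adjusted p = 0.193). NFAT5 (ENSG00000102908, chromosome 16, 69565966 to 69704666), the transcription factor of the osmotic response, stood at -0.04 ± 0.40, and its targets AKR1B1, SLC5A3 and SLC6A6, which make or import osmolytes, at 0.24 ± 0.53, -0.24 ± 0.45 and 0.08 ± 0.40. Each of these differences was smaller than its standard error. The log2 fold change of NFAT5 was 0.15 under total-count and upper-quartile scaling. SGK1 stood at 0.67 ± 0.73, and like NFAT5 and SLC5A3 it overlaps another gene. Heat shock chaperones had 21 of 25 members positive and a median of 0.26 (camera, adjusted p = 0.243). HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) measured 10.2 ± 6.79 against 2.51 ± 0.179 CPM (2.03 ± 0.72), with HSPA1B at 1.76 ± 0.67 and HSPH1 at 1.06 ± 0.43. Reads of the near-identical HSPA1A and HSPA1B may be split between them. Hypoxia and glycolysis genes had 17 of 25 positive and a median of 0.22 (camera, adjusted p = 0.288). ADM stood at 2.68 ± 0.98, TPI1 at 1.26 ± 0.49 and BNIP3L at 1.13 ± 0.53. Relative to the isotonic mean, hypertonic replicates 1 and 2 were at 3.33 and 0.79 for ADM. They were at 1.48 and 0.99 for TPI1 and at 1.67 and 0.37 for BNIP3L. In these 3 lists 0 members passed over all genes, in edgeR or DESeq2, and 0 adjusted over the list alone in edgeR. Their medians under total-count scaling were 0.54, 0.51 and 0.46. The osmoadaptive median was -0.23 without hypertonic replicate 1, 0.54, past the threshold, without hypertonic replicate 2 and 0.51 without isotonic replicate 2. The heat shock median was 0.49, past the threshold, without hypertonic replicate 1, -0.19 without hypertonic replicate 2, and 0.14 and 0.56 without isotonic replicates 1 and 2. The hypoxia median was 0.02 and -0.016 without hypertonic replicates 1 and 2, and 0.12 and 0.44 without isotonic replicates 1 and 2.

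Since expressed protein-coding genes were lower as a class with TMM scaling, the lists were also tested against those 4828 genes alone. This comparison was chosen after seeing the data. Of 21 lists with enough members, 5 passed: ribosomal proteins (adjusted p = 0.010) and SR proteins (adjusted p = 0.00728) were lower than the class. Heat shock chaperones (adjusted p = 1.05e-06), osmoadaptive genes (adjusted p = 0.00294) and hypoxia genes (adjusted p = 0.00354) were higher. The other lists described as lower above did not pass here. With an estimated correlation 0 of the 21 passed, with adjusted p of 0.916 for ribosomal proteins, 0.861 for heat shock and osmoadaptive genes and 0.787 for SR proteins and hypoxia genes. Counts of lists without 1 library were 3 (hypertonic replicate 1), 6 (hypertonic replicate 2), 11 (isotonic replicate 1) and 8 (isotonic replicate 2). Without hypertonic replicate 1 the ribosomal (adjusted p = 0.282), osmoadaptive (adjusted p = 0.941) and hypoxia (adjusted p = 0.282) calls were lost, and without hypertonic replicate 2 the heat shock (adjusted p = 0.0649) and SR (adjusted p = 0.605) calls. The class was not matched on gene length. Ribosomal genes (median length 5.22 kb) had medians of -0.89 and -0.55 in hypertonic replicates 1 and 2. SR genes (19.1 kb) had -0.85 and -0.55. Protein-coding genes with an isotonic RPKM of at least 1 had -0.83 and -0.19 under 5 kb, and -1.26 and -0.16 at 5 to 20 kb. In replicate 1 the lower ribosomal and SR levels were thus not separated from gene length. Against all tested genes 15 of the 24 lists passed, all 15 lower. With an estimated correlation 0 passed, and with fry 0. With same-strand overlapping genes left out the median was -0.71 for translation factors, -0.47 for Integrator and Mediator subunits and -0.39 for p53 targets. With the replicate number as a block it was -0.50 for Integrator and Mediator subunits, -0.52 for DNA replication, -0.47 for ribosome biogenesis and -0.40 for ATF4 targets, and with the length trend removed -0.09 for ATF4 targets.

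Cell volume and ion transport genes had 15 of 24 members positive, with a median of 0.12 and a mean of 0.14 while camera's direction was down (adjusted p = 0.833). SLC8A1 was at 0.97 ± 0.66. The median was -0.14 without hypertonic replicate 1, -0.07 without isotonic replicate 1 and 0.22 without isotonic replicate 2, 0.32 and 0.29 under total-count and upper-quartile scaling, and -0.05 with the replicate number as a block. Cholesterol genes had a median of -0.13 (23 tested, 15 negative; adjusted p = 0.113). ACAT2, downstream of an active neighbour, stood at 0.96 ± 0.51. The list passed without hypertonic replicate 1 (-0.42) and without isotonic replicate 1 (-0.23), and its median was -0.05 without hypertonic replicate 2. Collagen and matrix genes had a median of -0.13 (26 tested, 18 negative; adjusted p = 0.0685). COL3A1 stood at -1.14 ± 0.59, TGFBI at -1.11 ± 0.51 and TIMP3 at -0.94 ± 0.45. The list passed without isotonic replicate 1 (-0.34). Its median was -0.44 and -0.28 without hypertonic replicates 1 and 2 and 0.03 without isotonic replicate 2. The cholesterol and collagen medians were 0.06 and 0.14 under total-count scaling. Replication-dependent histone genes had a median of -0.33 (32 of 85 tested, 22 negative; adjusted p = 0.0683). HIST1H4B stood at -1.40 ± 0.66, HIST1H4E at -1.02 ± 0.54 and HIST1H2BE, downstream of an active neighbour, at 1.92 ± 0.66. The list passed without isotonic replicate 2 (-0.42) and with overlapping genes left out (-0.38). Its median was -0.08 and -0.61 without hypertonic replicates 1 and 2, -0.23 without isotonic replicate 1 and -0.10 under total-count scaling. In these 4 lists 0 members passed over all genes, in edgeR or DESeq2, and 0 adjusted over the list alone in edgeR.

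Markers of other cell types were mostly untested or low. Of 14 blood cell markers 2 were tested, PTPRC at 5.43 ± 0.680 against 3.31 ± 0.723 CPM (SD, n = 2 each) and MS4A1 at 0.958 ± 0.757 against 0.320 ± 0.380 CPM. Of 12 epithelial markers 5 were tested, with a median of 0.47 (camera, adjusted p = 0.288). GRHL2 stood at 1.54 ± 0.81, CDH1 at 0.87 ± 0.80 and EPCAM at 0.47 ± 0.76. Without isotonic replicate 1 this list passed, with a median of 1.53, and the median was 1.31 without hypertonic replicate 1 and 1.19 without isotonic replicate 2. Of 13 liver and neuron markers 5 were tested, with a median of 0.09 (camera, adjusted p = 0.44). The median was 0.16 to 0.66 with 1 library left out and -0.11 with the length trend removed. APOA1 (chromosome 11, 116835751 to 116837950) measured 0.832 ± 0.101 against 0.0381 ± 0.0191 CPM (SD, n = 2 each), a log2 fold change of 4.42 ± 1.01 (edgeR adjusted p = 0.193 over all genes, 0.00877 adjusted over the list alone), and lies downstream of a more active gene on its strand. RBFOX3 measured 20.1 ± 9.83 against 15.2 ± 1.86 CPM and GAD1 5.95 ± 2.26 against 7.26 ± 2.95 CPM. Adjusted over the list alone, APOA1 was the 1 member to pass in these 3 lists, and 0 passed over all genes. The tables held 0 mitochondrially encoded genes, and of 32 spliceosomal snRNA genes 0 passed the expression filter.

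**Figure D1:**
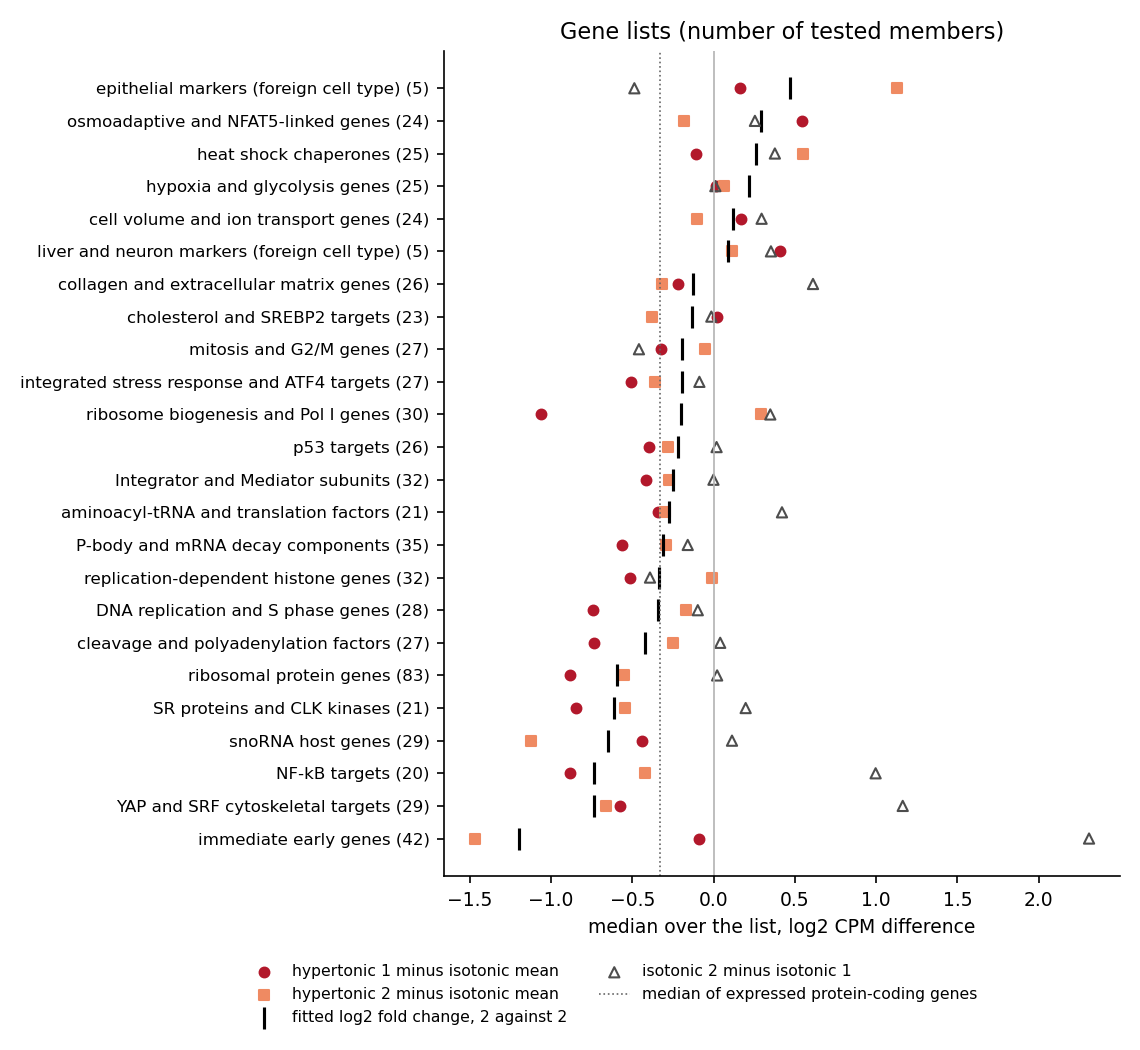
Median log2 CPM difference over each gene list with at least 5 tested members (horizontal axis): the fitted log2 fold change of hypertonic over isotonic (bars), each hypertonic library minus the isotonic mean (filled points), isotonic replicate 2 minus replicate 1 (open triangles) and the median of expressed protein-coding genes (dotted line at -0.33). The fitted medians run from -1.20 for immediate early genes to 0.47 for epithelial markers, and those of the 15 lists past the camera threshold lie below 0 with TMM scaling, while the p53, mitosis, ribosome biogenesis and ATF4 medians were above 0 under total-count or upper-quartile scaling.

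Genes just downstream of a more active gene on their strand were higher in both hypertonic libraries. The class had 1204 genes and a median log2 fold change of 1.99, against 0.01 in the 14168 other genes without overlap, a difference of 1.98 (camera, p = 2.37e-69; p = 0.0220 with an estimated correlation). In 992 of the 1204 genes (82.4%) both hypertonic libraries lay above both isotonic ones and in 0.498% below, where chance gives 16.7% in each direction. Among the other genes 19.2% lay above. The neighbours upstream did not share the difference: over 1154 pairs their median was -0.16, and the downstream gene moved further up than its neighbour in 97.5% of pairs. MYOZ3 (chromosome 5, 150660874 to 150679365, plus strand), a gene of striated muscle, starts 1653 bp after the end of SYNPO and measured 14.0 ± 5.70 against 0.0381 ± 0.0191 CPM (SD, n = 2 each), a log2 fold change of 8.50 ± 0.98 with SYNPO at 0.37 ± 0.57.

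GRAMD2A (chromosome 15, 72159807 to 72197785, minus strand) starts 1243 bp after PKM, a glycolytic enzyme gene, and measured 41.1 ± 31.7 against 0.994 ± 0.0535 CPM (SD, n = 2 each), with PKM at 0.59 ± 0.40. MSH4 (chromosome 1, 75796882 to 75913238, plus strand), a gene of meiotic recombination, starts 1802 bp after RABGGTB and measured 107 ± 8.19 against 20.2 ± 1.08 CPM, a log2 fold change of 2.41 ± 0.42, while RABGGTB was at -2.19 ± 0.48. POLG2 (chromosome 17, 64477785 to 64497036, minus strand), 2579 bp after the helicase gene DDX5, measured 145 ± 61.3 against 25.6 ± 6.11 CPM, and PTPN6, 574 bp after C12orf57, 14.0 ± 0.0317 against 0.877 ± 0.512 CPM. GDF9, 8494 bp after AFF4, was at 3.56 ± 0.67, COX18, 3634 bp after ANKRD17, at 2.85 ± 0.53, CPLX4, 9173 bp after LMAN1, at 6.77 ± 1.07, and ASCL5, 7587 bp after TMEM9, at 7.11 ± 1.14. DDX25, 2727 bp after HYLS1, measured 25.5 and 7.78 CPM in the hypertonic libraries and 0 and 0.155 CPM in the isotonic ones. These 10 pairs were chosen after their values were seen, among downstream genes with a small p and a mean of at least 5 CPM. Each had an edgeR adjusted p of 0.192.

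The difference was largest within 10 kb of the neighbour. Genes under 5 kb away (757) had a median of 1.95, those at 5 to 10 kb (447) one of 2.08, those at 10 to 50 kb (1523) one of 1.11, and the 12645 others one of -0.06. Within 5 kb the medians of hypertonic replicates 1 and 2 were 2.03 and 1.60 relative to the isotonic mean, and at 5 to 10 kb they were 2.23 and 1.58. Per library, the median log2 CPM of the class minus that of the other genes was -0.88 and -1.85 in the hypertonic and -3.46 and -3.16 in the isotonic libraries (exact permutation test, n = 2 per group, p = 0.333, the smallest possible). Of the class 709 genes were higher and 0 lower at an unadjusted p under 0.05, 0 passed the edgeR threshold over all genes, and 128 of the 200 genes with the smallest p belonged to it. The difference was 1.05 with neighbours at least as high as the gene and 2.82 with neighbours at least 10 times as high, a choice that also selects genes of a lower isotonic level, and the 2 were not separated here.

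**Figure D2:**
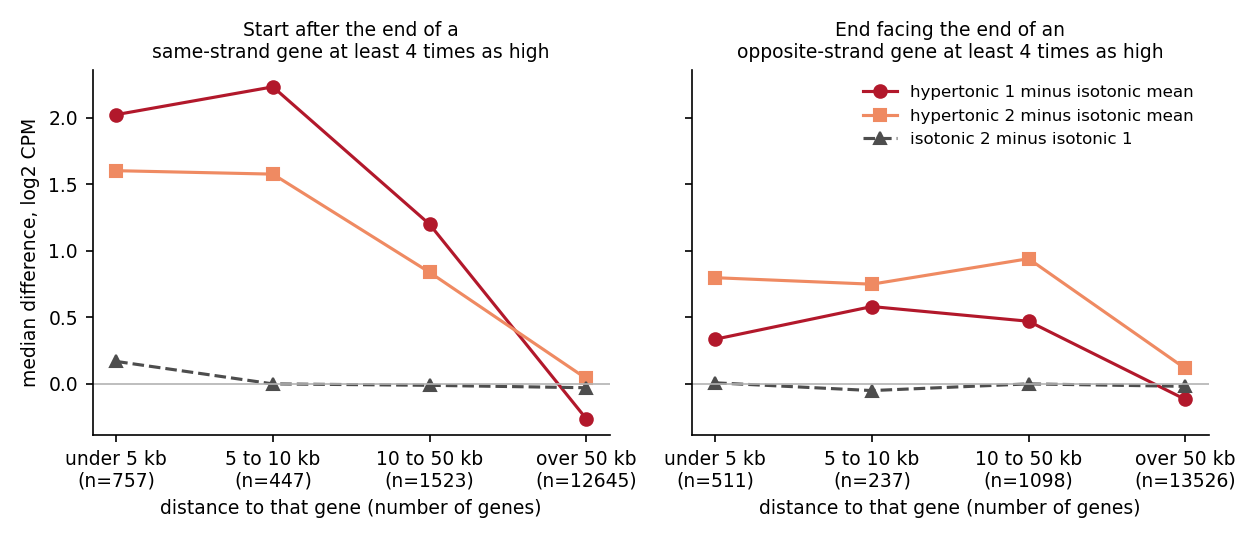
Median difference in log2 CPM (vertical axis) of each hypertonic library from the isotonic mean, and of isotonic replicate 2 from replicate 1, by distance in kb to a more active neighbour upstream on the same strand (left) or convergent on the other strand (right). Upstream, the hypertonic medians fall from 2.03 and 1.60 under 5 kb to -0.26 and 0.04 over 50 kb, and facing a convergent gene they are 0.34 and 0.80 under 5 kb and -0.12 and 0.12 over 50 kb.

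Genes whose end faced the end of a more active gene on the opposite strand differed less. The 511 genes of this class had a median log2 fold change of 0.54 against 0.06 in the others, a difference of 0.47 (camera, p = 2.35e-06; p = 0.0699 with an estimated correlation). Both hypertonic libraries lay above both isotonic ones in 40.9% of them and below in 6.07%, where chance gives 16.7% each (exact permutation test of the class medians minus those of other genes, n = 2 per group, p = 0.333). Against genes matched on mean expression the difference was 0.16 and no longer passed the threshold, where the read-in class kept 1.67. It was 0.22 with neighbours at least as high as the gene, 0.27 with the ratio taken from all 4 libraries and 0.32 with read-in genes left out.

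Antisense counts took a higher share in both hypertonic libraries, in a comparison added after the data were examined. Over all genes they made up 8.60 and 6.03% of sense plus antisense counts in the hypertonic and 3.17 and 3.36% in the isotonic libraries (7.31 ± 1.82% against 3.27 ± 0.138%, SD, exact permutation test, n = 2 per group, p = 0.333). Of 9827 genes with tested antisense counts, 1905 rose and 1 fell at an edgeR adjusted p under 0.05. Their median log2 fold change was 1.31 over all 9827, and in 6186 (62.9%) both hypertonic libraries lay above both isotonic ones. These counts were scaled to the sense library sizes, so a higher antisense share alone raises most genes. The gene counts are therefore not separate evidence for that share. The antisense strand of BNIPL (chromosome 1, 151036570 to 151047600, plus strand), which faces the end of CDC42SE1 3370 bp away, measured 14.2 ± 3.58 against 0.197 ± 0.206 CPM (SD, n = 2 each), a log2 fold change of 6.003 ± 0.97 (edgeR adjusted p = 0.00667). ABCG8, 8041 bp from the end of LRPPRC, stood at 6.08 ± 1.01 (edgeR adjusted p = 0.00667). The 1 gene that fell was AC132825.8, with a log2 fold change of -2.94 ± 0.94 (edgeR adjusted p = 0.0388). These 3 genes were chosen after their values were seen.

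The antisense calls depended on the scaling. With TMM on the antisense counts themselves edgeR called 0 genes, and with the RPKM constant as library size 2356 of 9799. With the main library sizes limma-voom called 1034 and DESeq2 2289 of the 9827. The edgeR count was 0 without isotonic replicate 1, 136 without isotonic replicate 2 and 5134 without hypertonic replicate 2. Antisense fold changes varied with the distance to gene ends. Genes within 10 kb of a convergent active gene end (1198) had a median log2 fold change of 1.51, and those over 100 kb from one (1572) a median of 1.00, a difference of 0.51 (camera, p = 3.38e-06; p = 0.253 with an estimated correlation). Those at 10 to 50 kb (706) had a median of 2.05 and those at 50 to 100 kb (294) one of 1.23. Without hypertonic replicate 1 and isotonic replicate 1 in turn the difference was 0.13 and 0.11. In active genes within 10 kb of such an end (456) antisense counts were 24.6 and 12.9% in the hypertonic and 7.07 and 6.97% in the isotonic libraries. At 10 to 50 kb (530) they were 12.2 and 3.52% against 2.10 and 2.12%, and at over 100 kb (2681) 1.08 and 0.825% against 0.511 and 0.802%.

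**Figure D3:**
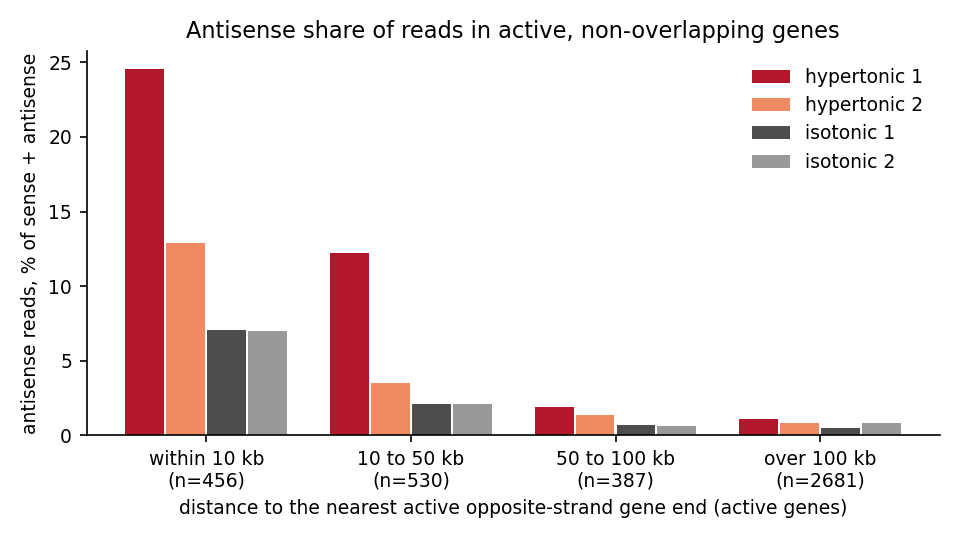
Antisense counts as a percent of sense plus antisense counts (vertical axis) in active genes without overlaps, by distance in kb from the nearest active gene end on the opposite strand, with 1 bar per library. Within 10 kb the hypertonic libraries reach 24.6 and 12.9% and the isotonic ones 7.07 and 6.97%, and over 100 kb all 4 lie between 0.511 and 1.08%.

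Along gene length the hypertonic libraries differed from the isotonic mean in opposite directions. Across 21238 genes the Spearman rho of log2 fold change with length was -0.02, from 0.15 in hypertonic replicate 1 and -0.22 in hypertonic replicate 2, with 0.03 between the isotonic libraries. Among 4941 protein-coding genes with an isotonic RPKM of at least 1, rho was 0.45 in hypertonic replicate 1 and -0.26 in replicate 2, with 0.14 between the isotonic libraries and 0.19 for the fitted fold change. In that set genes of 5 to 20 kb (1401) had medians of -1.26 in hypertonic replicate 1 and -0.16 in replicate 2, and genes over 100 kb (757) had 0.11 and -0.60. The median log2 CPM of genes over 100 kb (3646) minus that of genes under 20 kb (9701) was 5.01 and 3.94 in the hypertonic and 4.84 and 4.86 in the isotonic libraries (exact permutation test, n = 2 per group, p = 1). Without hypertonic replicate 1 rho was -0.21 and without hypertonic replicate 2 it was 0.10.

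**Figure D4:**
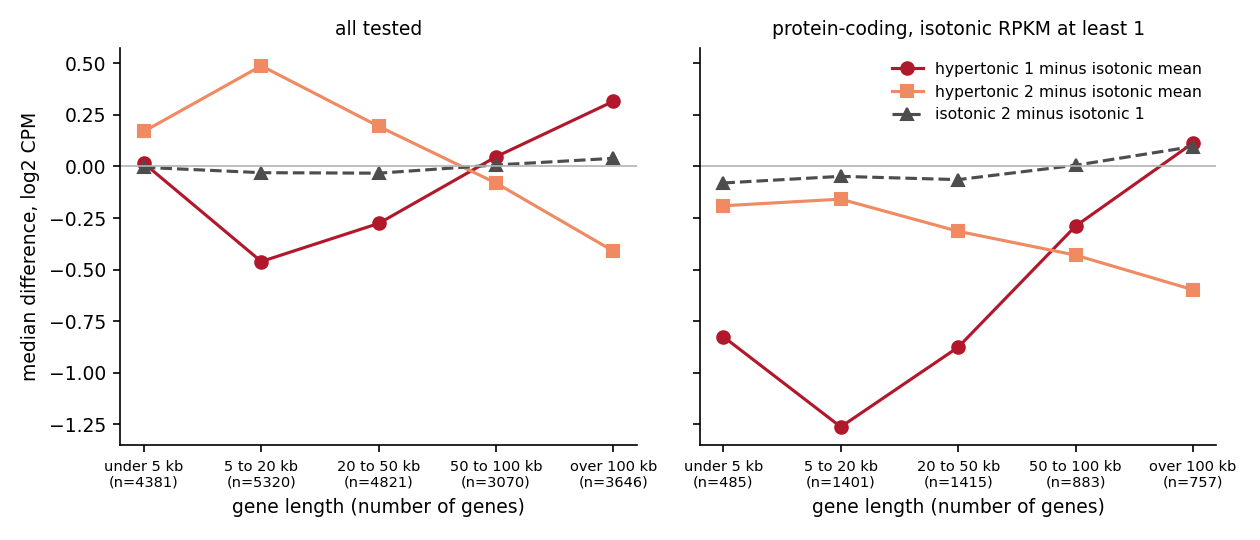
Median difference in log2 CPM (vertical axis) of each hypertonic library from the isotonic mean, and of isotonic replicate 2 from replicate 1, by gene length class in kb, for all tested genes (left) and protein-coding genes with an isotonic RPKM of at least 1 (right). In the right panel hypertonic replicate 1 lies at -1.26 for 5 to 20 kb and 0.11 over 100 kb, and hypertonic replicate 2 at -0.16 and -0.60.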

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

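All tests in this part were chosen after the results they bear on were seen. Reads outside the listed genes, taken as the part of each library's RPKM constant that the deposited gene counts did not account for, stood out because they belong to no comparison and exceeded the level of the isotonic controls. They made up 18.5 and 14.7% of the constant in the hypertonic libraries and 9.99 and 9.83% in the isotonic ones (16.6 ± 2.72% against 9.91 ± 0.112%, SD, exact permutation test, n = 2 per group, p = 0.333). What the constant counts is not stated, so these reads may include intergenic or mitochondrial ones. Antisense counts within genes moved the same way and were weighed with them. Weaker separation of the strands in the hypertonic libraries would raise the antisense share of every active gene alike, but active genes over 100 kb from a convergent active gene end gained 0.295 percentage points against 4.05 over all genes, which is 7.30% of the overall gain. Genomic DNA in the hypertonic libraries would add antisense reads evenly per kb, but the gain within 10 kb of a convergent end was 67.0 times the gain over 100 kb from one (42.1 to 181 times with 1 library left out). A candidate explanation is transcription that ran past gene ends in hypertonic medium onto the opposite strand of the next gene: it would raise antisense reads per kb further beside a convergent end (879 genes) than beside a divergent start (1081 genes). They stood at 3.23 and 1.86 times the isotonic mean at these places in hypertonic replicate 1, but at 1.57 and 1.53 times in hypertonic replicate 2. The smaller ratio of the 2 places was thus 1.03. This test compared fold rises, whereas the test for genomic DNA compared gains. By gain in antisense reads per kb, scaled to library size, the convergent end stood at 0.272 and the divergent start at 0.00866 (hypertonic minus isotonic mean). The isotonic means already differed in this order, at 0.194 and 0.0125, so the larger gain alone does not decide. The explanation stays open. Differences in the exposure or handling of the 2 groups of libraries were not tested.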

How the results depend on the processing

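Among the alternatives here, the removal of the length trend, the lists against expressed protein-coding genes, their upper-quartile scaling, RLE and total-count scaling, neighbour ratios from other libraries and protein-coding genes alone for the read-in class, the estimated correlation, the ratio from all 4 libraries and read-in genes left out for convergent genes, and all antisense settings were chosen after the data were seen. The count of 0 changed genes in edgeR (2316 at an unadjusted p under 0.05) stayed at 0 with RLE, total-count or upper-quartile scaling, limma-voom, a minimum of 1 CPM, the length and RPKM filter, overlapping genes left out, limma on log2 RPKM with each pseudocount, and the length trend removed. It became 731 with DESeq2 (706 higher), 916 of 37347 genes without a filter (869 higher), and 0 to 4919 with 1 library left out (6 and 4 without isotonic replicates 1 and 2). The cause was not tested. At the libraries' own spread the simulated test found 0% of 2-fold, 20.8% of 4-fold, 58% of 8-fold and 76% of 16-fold changes. This limits what a count of 0 can exclude. MYOZ3, with a fitted log2 fold change of 8.50, was not called (edgeR adjusted p = 0.192). The simulated shares may therefore overstate what the test finds in these data.

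The replicate number as a block gave 384 genes (380 higher), 14 lists and 1530 antisense genes; the p53 list was lost. Deviations of same-numbered libraries correlated at 0.0247, and with 2 pairs the numbers were not taken to pair the libraries.

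Of the 15 lists, 0 passed with an estimated correlation and 0 with fry. Against expressed protein-coding genes 5 passed, 0 with an estimated correlation and 3 to 11 with 1 library left out (8 without isotonic replicate 2); against all genes the counts were 10 to 17. Over all list medians and alternatives, 15 changed sign with a threshold passed before or after and 21 with neither passed. The cause was not tested. With total-count scaling the p53 median was 0.039, mitosis 0.043 and ribosome biogenesis 0.066, and with upper-quartile scaling the ATF4 median was 0.027. Without hypertonic replicate 1 ribosome biogenesis was 0.25, without isotonic replicate 1 mitosis was 0.063, and without isotonic replicate 2 immediate early genes were 0.71 and YAP and SRF targets 0.0041. The lowest medians with 1 library left out were -2.12 for immediate early genes, -1.11 for YAP and SRF targets, -0.45 for mitosis and -1.08 for ribosome biogenesis. In the comparison with expressed protein-coding genes, the ribosome biogenesis median was 0.21 without hypertonic replicate 1 and the hypoxia median -0.044 without hypertonic replicate 2. Osmoadaptive genes were at -0.066 and mitosis at 0.024 without isotonic replicate 1. Immediate early genes were at 0.71, ATF4 targets at 0.032 and collagen genes at 0.19 without isotonic replicate 2. These medians are set against 0, while the class itself had a median of -0.33 with all 4 libraries. Their sign is therefore not the direction tested against that class. Of 412 list values and alternatives 244 kept the sign of the median and the side of the threshold. This tally does not follow the direction that camera tested. Of 1575 for named genes 1449 kept the sign of the fold change and the side of the threshold. Another 107 newly passed and 19 changed sign with no threshold passed before or after.

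The read-in difference of 1.98 kept its direction and passed under each alternative run, from 1.05 to 2.82, and with 1 library left out from 1.53 to 2.46. The convergent difference of 0.47 no longer passed when matched on expression (0.16) or with an estimated correlation (0.47, p = 0.0699). The antisense count of 1906 became 0 with TMM on the antisense counts, 1034 with limma-voom, 870 with overlapping genes left out, where 3770 genes were tested, and 0 to 5134 with 1 library left out. The antisense difference near gene ends (0.51) did not pass with an estimated correlation (0.51, p = 0.253). The cause was not tested. The length rho ranged from -0.21 to 0.10 with 1 library left out.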

Other observations

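All tests in this part were chosen after the results they bear on were seen, except the matched comparisons of convergent and of downstream genes, which were planned, and the comparison with genes ahead of a neighbour, whose bounds were set before its result was seen. Gene types outside the lists differed in direction. The 168 tested snoRNA genes had a median log2 fold change of -0.71. In 47.6% of them both hypertonic libraries lay below both isotonic ones and in 0.595% above, where chance gives 16.7% in each direction. Expressed protein-coding genes showed 38.7% below and 5.32% above. The list of genes that host snoRNAs in their introns was also lower, with a median of -0.65. Reads of host transcripts over these introns were not told apart from snoRNA reads here, so the 2 results may not be independent. Genes annotated as antisense transcripts (1724) had a median of 0.70, with 44.6% above, lincRNAs (2027) one of 0.50, with 36.5% above, and 56 transcribed unitary pseudogenes one of 1.19, with 58.9% above. Protein-coding genes (14523) had a median of -0.05 and 37 miRNA genes one of -0.49. These medians were not tested. Of the antisense transcripts 23.0%, of the lincRNAs 16.8% and of the unitary pseudogenes 41.1% lay within 50 kb downstream of a more active neighbour, against 11.5% of protein-coding genes.

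The hypertonic libraries differed from each other in some stress genes. SLC38A2, the amino acid transporter of the osmotic response, chosen after its values were seen, measured 2383 and 146 CPM in hypertonic replicates 1 and 2 and 413 and 407 CPM in the isotonic libraries, a log2 fold change of 1.63 ± 0.96 (SE). SGK1 measured 116 and 24.3 CPM against 23.99 and 63.7 CPM, and HSPA1A 5.41 and 15.0 CPM against 2.38 and 2.63 CPM.

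Genes just downstream of a more active gene were higher in both hypertonic libraries, by 1.98 on the log2 scale over other genes. Choosing genes for low isotonic counts would raise their fold changes, but with genes chosen on isotonic replicate 1 and compared with isotonic replicate 2 the difference was 1.79. A higher level of the upstream gene would need that gene to rise, and its median was -0.16. Reads of the neighbour counted without strand would raise genes facing a convergent neighbour alike, and these differed by 0.16 when matched on expression, against 1.67 for the downstream genes. A candidate explanation is that transcription in hypertonic medium continued past gene ends into the next gene, a hypothesis under which genes ahead of the start of an equally more active neighbour would differ far less. In hypertonic replicates 1 and 2 the medians were 1.92 and 1.38 for 809 genes after the end of such a neighbour and 0.18 and 0.63 for 290 genes ahead of its start. The smaller difference was 0.75, in hypertonic replicate 2, and did not reach the bound set for it, while replicate 1 did. The bound was a set share of the difference of 1.98, which rests on both hypertonic libraries and was 1.53 without hypertonic replicate 1. The hypothesis stays open, as do differences in exposure or handling.

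The hypertonic libraries differed from the isotonic mean in opposite directions along gene length, with a Spearman rho of 0.15 in replicate 1 and -0.22 in replicate 2. Count noise at unequal depth would let the gap of 0.374 change sign with the order of depth. After replicate 1 was thinned until it was as much shallower than replicate 2 as it had been deeper, which left 20161 of 21497 genes with at least 10 counts, the gap was 0.376. Thinning lowers the counts of all genes evenly, so it bears on count noise only and cannot exclude other differences between libraries of unequal depth. The isotonic libraries, at 41932649 and 21865138 sense counts, differed more in depth. Their rho was 0.03 over all tested genes and 0.14 among protein-coding genes with an isotonic RPKM of at least 1. An isotonic library mislabelled as hypertonic would have an isotonic antisense share, but the lower of the hypertonic shares was 1.79 times the higher isotonic one. A different length of exposure of the hypertonic replicates may account for the gap; the labels give no exposure time, and this was not tested.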
